A study of Mus musculus with 2 samples.

How the data were processed

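Droplet libraries of sorted Tomato-positive skull cells were made with the 10x Genomics Chromium 5' kit, version 2, per the labels' protocols, 1 from each of 2 genotypes. The authors deposited, for each library, a filtered matrix of raw UMI counts per gene and cell barcode with its gene and barcode lists, and Cell Ranger 6.0.0 and the mouse build mm10 are named in the submitters' processing notes. The annotation used for counting is not given in the sources used here, nor is the number of animals per library. Both gene lists held the same 32285 genes. Coordinates came from GENCODE M21 on GRCm38, matched by Ensembl identifier for 32158 of these genes and for 319 of the 319 genes named or listed. No cell annotation by the authors was used here.

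Cells were kept with at least 1000 UMIs, at least 500 genes and at most 10% mitochondrial UMIs, which left 7788 control and 9623 mutant barcodes. Doublet scores were computed per library with Scrublet in scanpy 1.11.5. Its automatic threshold marked 531 control cells but 1 mutant cell, which showed that it had not worked in the mutant library. The highest scores were then removed at 0.8% per 1000 cells in both libraries, 485 control cells (6.23%) and 741 mutant cells (7.70%). This rule was set after the automatic result was seen. It left 145461798 UMIs in 7303 control cells and 150551882 UMIs in 8882 mutant cells, with medians of 3974 and 3792.5 genes per cell; 207 control and 1373 mutant cells had under 5000 UMIs, so shallow cells limit the mutant library more. Counts were scaled to 10000 per cell, logged, reduced to 2000 variable genes and 30 principal components, and clustered jointly with 15 neighbours by the Leiden method (igraph 0.11.9) at resolution 1 with random seed 0 and no batch correction. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9 were used, with R 4.3.3.

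Clusters were named from 23 marker classes fixed before the data were examined. A marker was scored as its log2 fold over the median cluster, a class needed at least 3 detected markers, and a name needed a score 1 log2 unit above the next class; other clusters kept their number. This was the third of 3 naming rules tried. Each was looked at together with the class shares by library, and the third was kept, after the first 2 were seen, because chondrocyte-like cells are so many that a fold against all other cells hides their markers. The clusters were also made more than once, first for the doublet rule and then with exact neighbours for a repeatable result. Cycling genes mark a state and were not counted as another class. Shares under every naming rule are among the alternatives.

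UMIs were summed per library and class and divided by the total of the sum to give CPM. Counts have exact Poisson intervals, shares exact Clopper-Pearson intervals and ratios exact conditional binomial intervals, at 95%. A gene with no counts in a library was set to a floor of 3 counts for its ratio. With 1 library per genotype no p-value, standard error or number of changed genes was computed, and cells were not treated as replicates. Classes and clusters were compared where each library had at least 200 cells. The osteoblast-like cluster, single chondrocyte-like clusters and mesenchymal cells other than chondrocyte-like ones were added after the data were seen. Shares of cells with a UMI and cycling shares were computed after thinning each cell to 5000 UMIs, leaving out shallower cells, and macrophage-like cells were the background fixed beforehand for them. A cell counted as cycling with 3 or more genes of the S phase and mitosis list.

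Genes were named by a rule fixed before the data were examined. In mesenchymal cells these were the 12 highest and 12 lowest ratios among genes with at least 30 CPM in 1 library or more and at least 200 UMIs in all, with the same sign in at least a share of 0.75 of the classes. In each of the 4 largest mesenchymal classes or clusters they were the 4 highest and 4 lowest. Mitochondrial, ribosomal, haemoglobin, immunoglobulin, T cell receptor and sex-linked genes and unnamed gene models were left out. Members of the 22 gene lists were named where most extreme, together with Pth1r, and a few others, such as Col2a1, Spp1, Ihh and Bglap within single classes, were chosen after their values were seen. A list member was measured with at least 30 UMIs over both libraries. Each list median was set against 10000 random lists of the same size, drawn for each member among the 100 genes on either side of it in mean expression.

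Alternatives fixed before the data were examined were stricter cell filters (2000 UMIs, 1000 genes, 5% mitochondrial), all deposited barcodes, doublets kept, resolutions 0.5 and 2, each library clustered alone, a class per cell by marker score, and cells thinned or weighted equally. They also held classes weighted equally, other minimum counts for lists, unthinned cells or 2 genes for cycling, TMM factors from edgeR 4.0.16 and median-of-ratios factors. Equal weighting averaged only the mesenchymal classes and clusters with at least 200 cells in each library. It left out osteoblast-like cells and clusters 7, 8 and 17, so it also changed which cells counted. Added after seeing the data were the automatic doublet threshold, the first 2 naming rules, naming with no gap, clustering without the fixed markers, leaving out clusters of shallow cells, and thinning to 2000 UMIs for cycling. The ratio step was tested on counts simulated from these libraries for mesenchymal cells, on 16764 genes with 50 changed at each size. It called 40% of genes at 1.5-fold, 96% at 2-fold, 100% at 4-fold and 94% at 0.5-fold, and 0.7% of the 16564 unchanged genes, with 0 in the wrong direction. Both simulated libraries were Poisson draws from a shared profile. These rates therefore cover counting noise only, not differences between animals, dissections or cell mix.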

Results

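Single-cell RNA profiles were collected from the mouse skull in 2 libraries. Craniomaxillofacial tissue was digested and cells carrying the Tomato reporter, which marks cells with a history of Prx1Cre activity, were sorted as mesenchymal cells. One library came from the control genotype with Cre and reporter, and the other from animals with an added alteration of Pth1r, the receptor for parathyroid hormone and parathyroid hormone-related protein. The series concerns a skull deformity related to Pth1r, and the design sets the mutant library against the control library. The control file held 7914 barcodes with 162642692 unique molecular identifiers (UMIs), and the mutant file held 10013 barcodes with 170479349 UMIs. After filtering, 7303 control cells with a median of 19007 UMIs and 8882 mutant cells with a median of 16820 UMIs remained. With 1 library per genotype no difference had a replicate check and no test was made. Each ratio compares these libraries, and every interval is a 95% exact Poisson or binomial interval that covers counting error only.

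Pth1r itself (ENSMUSG00000032492, chromosome 9, 110722085 to 110747145, minus strand, GRCm38) was not lower in the mutant library as a whole. In mesenchymal cells together it stood at 78.5 CPM (summed UMIs of a gene scaled to the same total in each library) in control (77.0 to 79.9) and 219 CPM in mutant (216 to 221), a ratio of 2.79. In chondrocyte-like cells the level was 69.2 CPM in control and 322 CPM in mutant, a ratio of 4.65. The osteoblast-like cluster, where the gene was abundant in both libraries, had 504 CPM in control and 590 CPM in mutant. Meningeal fibroblast-like cells (29.2 and 26.0 CPM) and connective tissue fibroblast-like cells (38.9 and 33.3 CPM) differed by less than counting error. Within the chondrocyte-like clusters the order was mixed: cluster 2 had 210 and 214 CPM, cluster 3 had 31.3 and 102 CPM, and cluster 12, led by Col10a1, had 1230.4 CPM in control and 768 CPM in mutant. Cluster 12 held 58 of 4293 control and 543 of 2870 mutant chondrocyte-like cells, and 9085 of the 16374 mutant Pth1r UMIs of this class. The ratio of 4.65 therefore mixes the share of each cluster with the level within it.

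After thinning to 5000 UMIs per cell, 18.7% of control and 55.9% of mutant chondrocyte-like cells had a Pth1r UMI (48.8% and 74.7% unthinned). Thinning left out 152 control and 606 mutant shallower cells of this class. The planned background, macrophage-like cells, had few cells: 1 of 12 control cells (8.33%, 0.211 to 38.5) and 12 of 33 mutant cells (36.4%, 20.4 to 54.9), with median depths of 20547 and 4595 UMIs. Mural-like cells, taken as a further background after their values were seen, had 6.96% and 7.53%, with median depths of 13844.5 and 9098 UMIs. Against the macrophage-like shares, those in mutant cluster 9 (36.0%), tendon and ligament-like cells (23.6%) and cluster 6 (22.3%) were not set apart. Nor was the control chondrocyte-like share of 18.7%. Mutant macrophage-like cells held a mean of 17 thinned Col2a1 UMIs, against 0.596, 2.14 and 1.04 in those mutant groups. This background thus carried more cartilage RNA and cannot decide how much of their Pth1r was background. Their Col2a1 stood at 0.332%, 1.44% and 0.615% of the chondrocyte-like level. Against Pth1r at 123, 59.2 and 58.3 CPM, that argues against chondrocyte-like RNA as its main source. The labels do not say which part of Pth1r was altered and the kit reads the 5' end, so UMIs outside an altered part would still be counted. A level at or above control therefore does not check the genotype label.

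Chondrocyte-like cells took a smaller share of the mutant library, and osteoblast-like cells a larger one. Chondrocyte-like cells, marked by Col2a1, Matn1 and type IX collagen genes, made up 4293 of 7303 control cells (58.8%, 57.6 to 59.9) and 2870 of 8882 mutant cells (32.3%, 31.3 to 33.3). Osteoblast-like cells, marked by Ibsp and Ifitm5, made up 115 control cells (1.57%, 1.30 to 1.89) and 549 mutant cells (6.18%, 5.69 to 6.70). Meningeal fibroblast-like cells held 4.72% and 6.97%, connective tissue fibroblast-like cells 3.74% and 6.07%, and tendon and ligament-like cells 9.90% and 11.6%. Over the alternatives these differences ran from 1.36 to 8.32, 1.73 to 2.54 and -0.709 to 6.89 points, in that order. Of the named classes not counted as mesenchymal here, mural-like cells held 1.62% and 2.56%, and macrophage and monocyte-like cells 0.164% and 0.777%.

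Several clusters kept no class name because 2 marker classes scored alike in them, and together they held 19.5% of control and 33.5% of mutant cells. Cluster 7, led by the matrix metalloproteinase genes Mmp9 and Mmp13 with Ibsp and Tnfsf11, held 61 control cells (0.835%) and 848 mutant cells (9.55%). Cluster 17, led by cell cycle genes and Ibsp, held 2.12% and 6.06%. Cluster 9, led by Tnn and Ostn, held 7.59% and 7.84%, and cluster 6, led by Igfbp2 and Upk1b, held 6.81% and 6.55%. Cluster 8, led by Mfap5 and Ccn3, held 1.88% and 2.29%, and the shallow cluster 20, led by muscle genes such as Acta1, held 0.274% and 1.22%.

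Most control chondrocyte-like cells lay in clusters 0, 11, 3, 1 and 10, and most mutant ones in clusters 2, 12, 19, 3 and 22, so a cluster held mainly by 1 library can be that library rather than a type. Clustering without any marker gene gave chondrocyte-like shares of 57.7% and 33.1% and osteoblast-like shares of 1.51% and 5.84%. Over all alternatives the difference in chondrocyte-like share ran from -33.9 points at resolution 2 to -15.7 points with each library clustered alone. Sorting and tissue dissection can set all of these shares, and 15.5% of mutant against 2.83% of control cells had under 5000 UMIs. The size of the osteoblast-like share depended on clustering and naming, with 1.88% and 13.4% at a finer resolution and 12.1% and 29.6% where every cluster took the name of its best class.

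**Figure D1:**
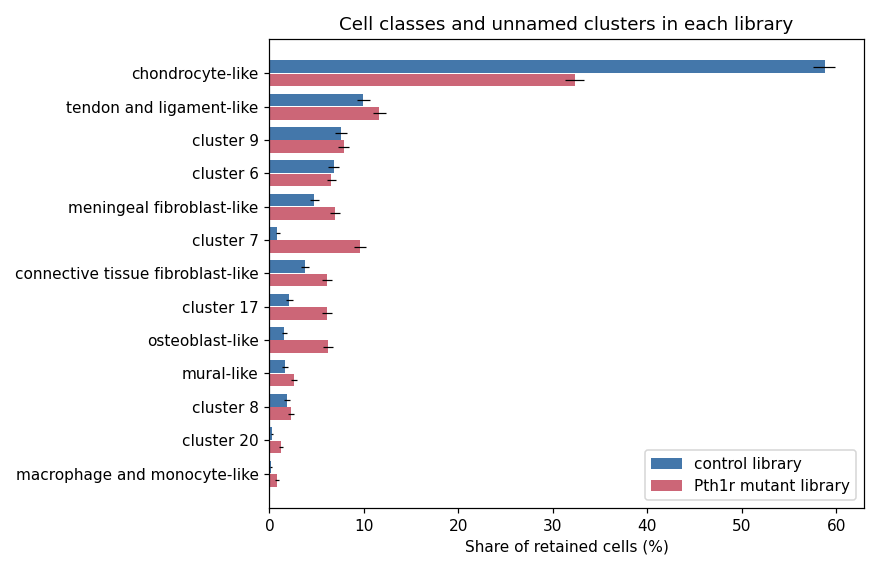
Share of retained cells (horizontal axis, percent) in each cell class or unnamed cluster (vertical axis) for the control library (blue) and the Pth1r mutant library (red), with exact 95% binomial intervals as black lines. The chondrocyte-like bar is at 58.8% in control and 32.3% in mutant, while the bars of cluster 7 and osteoblast-like cells are longer in the mutant library.

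After thinning to 5000 UMIs, cell cycle genes were seen in a smaller share of chondrocyte-like cells and a larger share of the other mesenchymal cells in the mutant library, and all of these differences depended on depth. In all, 15.3% of control mesenchymal cells (14.5 to 16.2) and 15.8% of mutant ones (15 to 16.7) had 3 or more genes of the S phase and mitosis list. In chondrocyte-like cells the shares were 638 of 4141 cells (15.4%, 14.3 to 16.5) and 177 of 2264 cells (7.82%, 6.75 to 9), and in the other mesenchymal cells 15.1% (13.8 to 16.5) and 19.4% (18.3 to 20.5). Connective tissue fibroblast-like cells had 19.2% and 10.5%, while cluster 9 had 10.0% and 14.8%. Unthinned, the mesenchymal shares were 43.0% and 38.4%, the chondrocyte-like shares 38.9% and 27.4%, and those of the others 49.2% and 44.0%. Thinning left out 606 mutant chondrocyte-like cells, of which 148 had 3 or more of these genes unthinned, 142 of them in the shallow cycling cluster 22, against 5 of 152 control cells left out. Thinned to 2000 UMIs, which was chosen after seeing the data and kept more of them, the chondrocyte-like shares were 8.49% (7.67 to 9.37) and 6.90% (5.97 to 7.92), and those of all mesenchymal cells 8.19% (7.56 to 8.85) and 9.41% (8.78 to 10.1).

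Across mesenchymal cells as captured, the 12 highest ratios held Col10a1 of hypertrophic cartilage, several bone genes and the Hedgehog targets Hhip and Ptch1. Ramp1 had 9 CPM in control (8.51 to 9.50) and 51.8 CPM in mutant (50.6 to 52.9), a ratio of 5.75. Hhip, which encodes a Hedgehog-binding protein and is itself a Hedgehog target, had 12.2 and 69.3 CPM (5.68-fold higher), and Ptch1, a Hedgehog receptor and target, 9.70 and 36.7 CPM. Col10a1, the collagen of hypertrophic cartilage, had 204 and 999 CPM (4.89-fold higher), with Mef2c, a transcription factor of chondrocyte hypertrophy, at 27.5 and 96.6 CPM. Of bone genes, Ibsp (bone sialoprotein) had 661 and 2675.9 CPM, Sp7 (osterix) 12.5 and 49.7 CPM, Alpl (tissue-nonspecific alkaline phosphatase) 125 and 417 CPM, and Tnfsf11 (the osteoclast-inducing ligand RANKL) 17.6 and 58.3 CPM. Fxyd7 (8.86 and 41.2 CPM), the lipase gene Lpl (11.8 and 50.3 CPM) and Spon1 (12.3 and 45.7 CPM) completed the 12 highest ratios.

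The 12 lowest ratios were led by genes of cartilage. Ucma, which encodes a secreted cartilage matrix protein, had 544 CPM in control (541 to 548) and 41.0 CPM in mutant (39.9 to 42.0), 13.3-fold lower. Trf, the transferrin gene, had 48.8 and 4.10 CPM, 11.9-fold lower. Epyc, a cartilage proteoglycan gene, had 930 and 150 CPM, and Matn1, the gene for matrilin 1, 7326.1 and 1706.2 CPM. Lower levels were also counted for Edn2 (36.9 and 6.35 CPM), Serpina3n (90.3 and 15.6 CPM), Meltf (237 and 43.3 CPM) and the transcription factor gene Sox8 (34.6 and 6.51 CPM). The others were Ccn6 (36.1 and 6.97 CPM), the long noncoding RNA Pantr1 (33.6 and 7.33 CPM), Pon3 (35.9 and 10.3 CPM) and Scrg1 (214 and 62.8 CPM). Because the share of chondrocyte-like cells differed, these ratios mix composition with levels per class. With classes of at least 200 cells in each library weighted equally, the log2 ratio of Ibsp went from 2.02 to 0.19. That of Lpl went from 2.09 to 0.93 and that of Alpl from 1.74 to 0.74. This weighting left out osteoblast-like cells, whose absence can add to these falls. All 24 genes kept their direction, which their choice by extreme ratio and like sign across classes made likely beforehand. Over the alternatives, the log2 ratio ran from -3.815 to -2.212 for Trf, -2.698 to -1.631 for Epyc and -1.868 to -0.836 for Pon3.

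**Figure D2:**
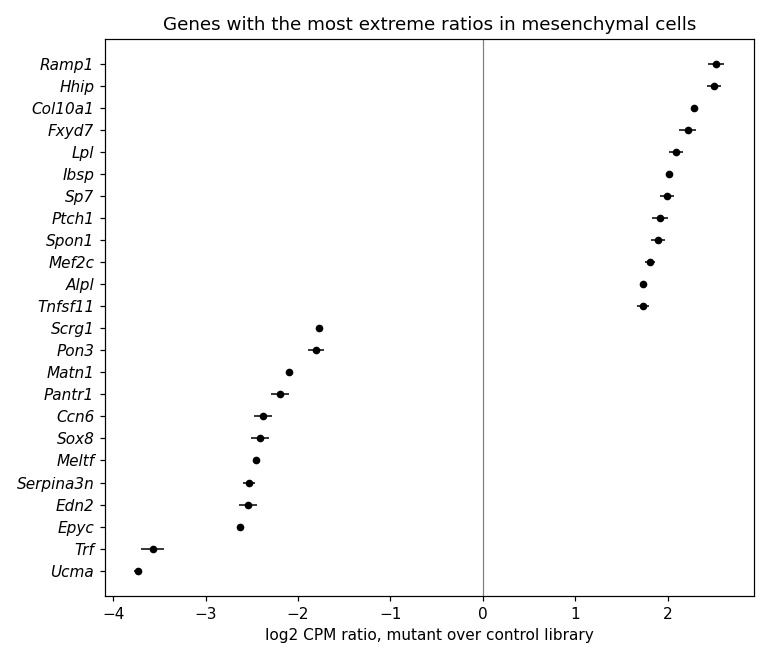
Log2 ratio of summed CPM, mutant over control library (horizontal axis), for the 12 highest and 12 lowest genes in mesenchymal cells (vertical axis); points are ratios and lines exact 95% counting intervals, some shorter than the point. Ramp1 lies at 2.52 at the top and Ucma at -3.73 at the bottom.

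Of the gene lists fixed before the data were examined, those of bone formation lay high in mesenchymal cells as captured. Their medians were near 0 with classes of at least 200 cells in each library weighted equally. That weighting left out osteoblast-like cells and clusters 7 and 17, so the fall can come partly from their absence. A member counted as higher or lower at a 1.5-fold ratio with an interval excluding 1, and a percentile sets the list median against 10000 random lists of like expression. Of 18 mineralizing osteoblast genes, 10 were higher and 2 lower (median log2 0.68, percentile 100), but the median was 0.07 with classes weighted equally and 0.07 (percentile 91.15) in mesenchymal cells other than chondrocyte-like ones. Mepe (0.726 and 7.06 CPM) and Phex (3.53 and 19.4 CPM) were highest, and Bglap, the osteocalcin gene, went the other way (16 and 1.02 CPM). Of 16 osteogenic transcription factors, 8 were higher and 0 lower (0.55, percentile 100), among them Dlx5 (13.5 and 42.9 CPM) beside Sp7, but with classes weighted equally this median was -0.04. Of 16 suture stem cell genes, 5 were higher and 0 lower (0.41, percentile 100), with Gli1 at 8.08 and 26.9 CPM and Cd200 at 22.6 and 60.8 CPM. Of 18 fibrillar collagen and matrix genes, 3 were higher and 0 lower (0.30, percentile 100), among them Tnc (192 and 318 CPM) and Col1a1 (8274.5 and 13338.5 CPM).

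Cartilage matrix genes were lower across mesenchymal cells as captured, with 2 of 16 higher and 9 lower (median log2 -0.75, percentile 0). The median was -0.11 with classes weighted equally, so its size depended on which classes counted and with what weight. Cnmd, the chondromodulin gene, had 3283 and 1029.5 CPM and Col9a3 6579.4 and 2637.6 CPM, while Col10a1 and Chad (375 and 747 CPM) went the other way. FGF pathway genes had 1 of 15 higher and 5 lower (-0.38, percentile 0), with Dusp6, a feedback target of FGF signalling, at 48.6 and 25 CPM and Fgf7 going the other way at 8.08 and 20.2 CPM; this median was -0.08 with classes weighted equally. Hypoxia and glycolysis genes had 1 of 12 higher and 3 lower (-0.35, percentile 0.02), with the glucose transporter gene Slc2a1 at 166 and 92.1 CPM and Bnip3 at 158 and 91.5 CPM. Craniosynostosis genes had 2 of 16 higher and 0 lower (-0.11, percentile 1.92), with Alx4 at 8.61 and 5.79 CPM and Twist1 at 215 and 334 CPM.

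Signalling lists were mostly above the middle of the random lists in mesenchymal cells. Wnt pathway genes had 7 of 20 higher and 1 lower (median log2 0.43, percentile 100), including Sfrp4 (7.16 and 19.4 CPM) and Tcf7 (14.7 and 29.1 CPM), with Sfrp1 going the other way (61.5 and 39.9 CPM); with classes weighted equally the median was -0.00028. Notch pathway genes had 5 of 10 higher and 0 lower (0.58, percentile 99.93), including Heyl (1.73 and 4.39 CPM) and the ligand gene Jag1 (12.3 and 28.4 CPM). BMP and TGF-beta pathway genes had 4 of 20 higher and 2 lower (0.23, percentile 99.84), with the antagonist gene Nog at 12.5 and 26.2 CPM and Tgfbi at 682 and 302 CPM; this median was 0.035 with classes weighted equally. Hedgehog pathway genes had 5 of 12 higher and 0 lower (0.19, percentile 96.64), including the ligand gene Ihh (12.9 and 51.9 CPM), Hhip and Ptch1, and this median was -0.12 with classes weighted equally. Genes of the PTH and cAMP-PKA response had 4 of 20 higher and 2 lower (0.31, percentile 99.98), with the protease gene Mmp13 at 57.6 and 116 CPM and Rgs2 at 118 and 53.8 CPM, and its median was -0.03 with classes weighted equally. The PTH1R ligand and receptor pathway had 2 of 11 measured genes higher and 0 lower (0.25, percentile 98.72), the higher ones being Pth1r and Pthlh (8.47 and 18.9 CPM), the gene for the receptor's local ligand.

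The other lists covered growth factor carriers, cell states and checks of the samples. IGF axis genes had 4 of 12 higher and 1 lower (median log2 0.26, percentile 99.93), with Igfbp3 at 139 and 267 CPM and Dlk1 at 4686.4 and 1868.7 CPM. Osteoclast regulators had 2 of 10 higher and 0 lower (0.49, percentile 99.99), namely Tnfsf11 and the chemokine gene Ccl2 (56.3 and 99.9 CPM). Adipocyte differentiation genes had 5 of 13 higher and 1 lower (0.24, percentile 97.79), with Pparg at 2.5 and 7.34 CPM and Fabp4 at 34.9 and 16.2 CPM, and a median of 0.79 with all deposited barcodes and 0.14 with doublets kept. S phase and mitosis genes had 0 of 16 higher and 2 lower (-0.09, percentile 2.87), with Ube2c at 69.9 and 43.6 CPM; the median was 0.10 with cells weighted equally and -0.62 with classes weighted equally, so it gave no stable direction. Dissociation stress genes had 0 of 18 higher and 1 lower (-0.07, percentile 3.47), with Ier3 at 558 and 371 CPM. Interferon response genes had 1 of 8 higher and 0 lower (0.02, percentile 42.84), and blood cell RNA 3 of 8 higher and 1 lower (0.15, percentile 67.32). The sex-linked list had Xist at 287 and 65.3 CPM and the Y-linked Ddx3y at 27.3 and 65.3 CPM (4 of 6 higher, 2 lower, 1.21, percentile 100), so the libraries differed in the mix of male and female cells. With classes weighted equally, 3 lists in place of 13 lay in the highest 2.5% of the random lists, and medians were 0.07 for Notch pathway genes, 0.06 for suture stem cell genes and the PTH1R pathway, 0.08 for the IGF axis, and 0.03 for fibrillar collagen and osteoclast regulators.

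Within chondrocyte-like cells of all clusters pooled, Col10a1 of hypertrophic cartilage and most measured mineralizing osteoblast genes were higher in the mutant library. Col10a1 (ENSMUSG00000039462, chromosome 10, 34389981 to 34397085, plus strand, GRCm38) had 332 CPM in control and 2873.5 CPM in mutant. After thinning, 69 of 4141 control cells (1.67%, 1.30 to 2.10) and 602 of 2264 mutant cells (26.6%, 24.8 to 28.5) had a Col10a1 UMI, with unthinned shares of 2.66% and 31.9%. The planned background, macrophage-like cells, had 0 of 12 control and 12 of 33 mutant cells with a UMI (36.4%, 20.4 to 54.9), so this share alone does not set the mutant cells above background; mural-like cells, a background taken after their values were seen, had 0.870% and 2.05%. The mean was 14.3 thinned UMIs per mutant chondrocyte-like cell and 1.58 per mutant macrophage-like cell. Of genes chosen after their values were seen, Ihh, the ligand made by prehypertrophic chondrocytes, had 19.6 and 134 CPM, and Spp1, the osteopontin gene, 564 and 5334 CPM. The 4 highest ratios were those of Mmp13 (3.27 and 51.0 CPM), Parm1 (2.24 and 33.5 CPM), Ramp1 (2.33 and 34.7 CPM) and Phex (2.47 and 31.8 CPM), between 12.9-fold and 15.6-fold. The 4 lowest were A2m, the gene for alpha-2-macroglobulin (39.0 and 1.73 CPM, 22.5-fold lower), Trf (75.9 and 7.48 CPM), Ucma (884 and 109 CPM, 8.08-fold lower) and Fbxo2 (40.8 and 5.35 CPM). Col2a1, the main cartilage collagen gene, was close in both, at 33410.9 and 30629.2 CPM. The class drew on different clusters in each library, as given with the shares, and with doublets kept the log2 ratio of Mmp13 was 2.64 in place of 3.96.

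By list, 12 of 16 measured mineralizing osteoblast genes were higher and 1 lower in chondrocyte-like cells (median log2 1.41, percentile 100). Single clusters gave less: cluster 3 had 0.74 (8 of 15 higher, 0 lower), and the Col10a1-led cluster 12, with 58 control cells, went the other way at -0.42 (2 of 16 higher, 7 lower, percentile 0), so the mix of clusters can add to the pooled median. After thinning, 1.04% of control and 9.58% of mutant chondrocyte-like cells had an Ibsp UMI. The shares also rose in meningeal fibroblast-like cells (0.59% and 5.67%) and mural-like cells (0% and 5.48%). Mean thinned Ibsp UMIs in the mutant library were 1.19, 0.115 and 0.192, in that order. RNA carried over from osteoblast-like cells, more numerous in the mutant library, was not tested and can add to these counts. Of 16 S phase and mitosis genes, 14 were lower and 0 higher (-1.08, percentile 0), but within clusters the medians were 0.13 in cluster 1, -0.07 in cluster 2, 0.04 in the cycling cluster 10 and -0.54 in cluster 3. Among these, Ccnb2 had 31.4 and 10.2 CPM and Cdk1 70.3 and 26.2 CPM. Wnt pathway genes had 13 of 18 higher and 1 lower (0.75, percentile 100), with the feedback inhibitor gene Notum at 45.8 and 124 CPM, but the median was -0.04 in cluster 3, the only one with 200 cells of each library, and -0.16 in cluster 12, against 0.60 in cluster 2 and 0.92 in cluster 1. FGF pathway genes had 1 of 13 higher and 7 lower (-0.62, percentile 0), with Etv4 at 3.25 and 0.827 CPM and medians of -0.70 in cluster 3 but -0.18 in cluster 2 and -0.11 in cluster 12, which held most mutant cells of the class. Dissociation stress genes, which respond to handling, had 0 of 18 higher and 4 lower (-0.31, percentile 0.05), so a difference in handling or quality was not ruled out for this class. Cartilage matrix genes had 5 of 16 higher and 3 lower (0.00, percentile 17.04): Comp had 1786.8 and 4101.4 CPM, while Matn1 had 12018.1 and 4911.3 CPM. The Hedgehog pathway list split, with 4 of 11 higher and 4 lower (-0.34, percentile 1.17); Ptch1 (5.10 and 30.7 CPM) and Gli1 (3.59 and 16.4 CPM) were higher and Gas1 (48.4 and 9.03 CPM) was lower.

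In tendon and ligament-like cells, marked by Scx, Tnmd and Thbs4, the Hedgehog target Hhip was higher (19.4 and 67.5 CPM, 3.48-fold), as were Fst, the follistatin gene (13.9 and 43.4 CPM), Trh (11.8 and 33.9 CPM) and Tnfsf11 (18.1 and 50.1 CPM). The lowest ratios were those of Cnmd (175 and 20.8 CPM, 8.43-fold lower), Cd74 (42.2 and 5.14 CPM), Mia (170 and 30.6 CPM) and Col9a1 (45.6 and 12.6 CPM). Notch pathway genes had 4 of 7 measured genes higher and 0 lower (median log2 0.70, percentile 100), among them the targets Hey1 (7.76 and 17.9 CPM) and Hes1 (57.3 and 92.9 CPM). Hypoxia and glycolysis genes had 1 of 12 higher and 5 lower (-0.49, percentile 0), with Bnip3 at 54.7 and 24.2 CPM and Pgk1 at 267 and 148 CPM. Free RNA from chondrocyte-like cells, more numerous in the control library, can add cartilage counts to this and every other class; Matn1 had 23.7 and 5.29 CPM here. With all deposited barcodes kept, the class gave the opposite direction for Trh (log2 -1.04), Cnmd (0.89), Cd74 (0.54) and Col9a1 (0.51), and smaller values for Mia (-0.25 in place of -2.47) and Tnfsf11 (0.79 in place of 1.47). That setting alters the filter, doublets and clusters at once, and which of them moved these 6 ratios was not tested.

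Cluster 9, led by Tnn and Ostn, had lower summed levels of bone matrix genes in the mutant library. Of 16 mineralizing osteoblast genes, 0 were higher and 8 lower (median log2 -0.96, percentile 0): Ibsp had 253 and 89.3 CPM, Ifitm5 87.1 and 26.8 CPM and Bglap 29.0 and 1.07 CPM. Matn1 (62.3 and 6.10 CPM) and the Wnt inhibitor gene Wif1 (181 and 59.5 CPM) were the other named low genes. Higher were Fxyd7 (4.49 and 63.9 CPM, 14.2-fold), Lpl (6.16 and 32.1 CPM), Igfbp7 (158 and 812 CPM) and Aldh1a2, which encodes a retinoic acid-making enzyme (10.6 and 33.6 CPM). Notch pathway genes had 3 of 6 higher and 0 lower (0.68, percentile 100), with Hey1 at 10.4 and 31.0 CPM. Hedgehog pathway genes had 4 of 12 higher and 0 lower (0.12, percentile 96.07), with Hhip at 52.9 and 162 CPM. Ibsp and Ifitm5 also led this cluster, so their levels bear on how it was drawn, and the thinned log2 ratio of Aldh1a2 was 0.84 in place of 1.67. After thinning, 9.67% of control (7.33 to 12.5) and 8.22% of mutant cells (6.27 to 10.5) had an Ibsp UMI. For Spp1 the shares were 39.6% and 44.8%. Mean thinned UMIs were 0.907 and 0.361 for Ibsp and 11.1 and 3.93 for Spp1. Control cells with many UMIs can thus drive the lower sums of both genes. A Bglap UMI was seen in 11 of 548 control and 6 of 681 mutant cells.

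Cluster 6, led by Igfbp2 and Upk1b, had higher Hedgehog targets and a higher level of the Pth1r ligand gene. Hhip had 25 and 165 CPM (6.61-fold), Pthlh 11.2 and 70.4 CPM (6.30-fold), Aldh1a2 23.4 and 154 CPM and Pi15 2.64 and 44.7 CPM (16.9-fold). Gli1, a transcription factor and Hedgehog target, had 14.2 and 46.7 CPM and Ptch1 15.4 and 46.8 CPM, within 3 of 10 higher and 0 lower on that list (median log2 -0.11, percentile 18.31). Cartilage genes were lower, with 14 of 16 lower and 1 higher (-1.41, percentile 0), including Cnmd (864 and 175 CPM) and Matn1 (44.7 and 5.69 CPM). Pnoc (86.4 and 15.2 CPM), which also led the cluster, and Wfdc2 (57.7 and 13.1 CPM) were the other named low genes. Pthlh was higher in tendon and ligament-like cells as well (1.94 and 10.1 CPM), in cluster 9 (1.5 and 15.1 CPM) and in meningeal fibroblast-like cells (15.4 and 34.1 CPM), while chondrocyte-like cells had 10.3 and 12.7 CPM.

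**Figure D3:**
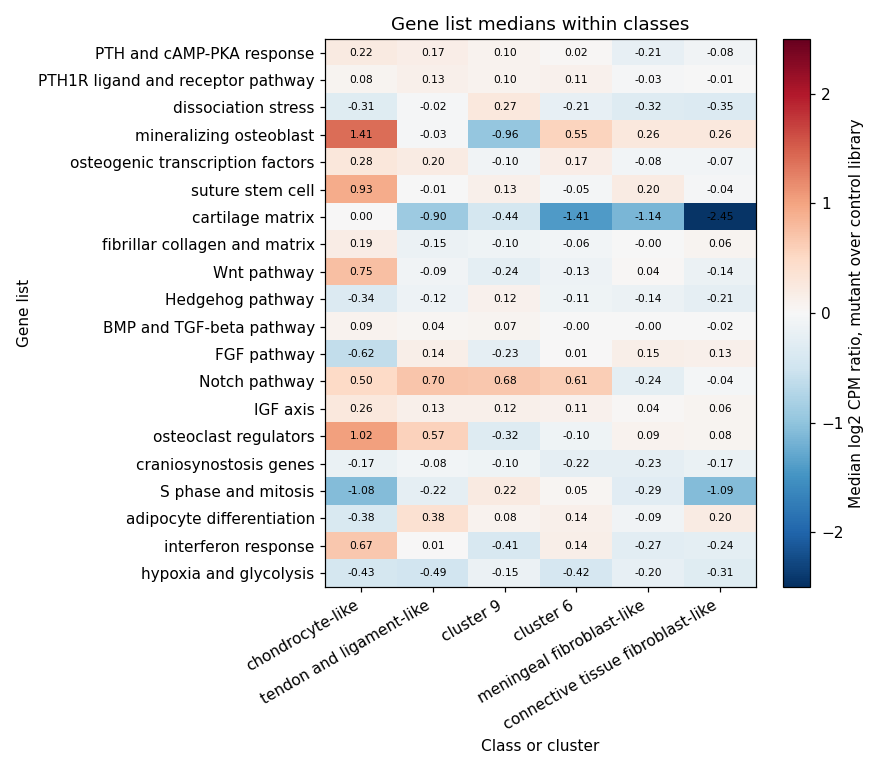
Median log2 CPM ratio, mutant over control library (colour scale, also printed in each cell), of 20 gene lists (vertical axis) in the 6 classes or clusters with at least 200 cells in each library (horizontal axis). Chondrocyte-like cells reach 1.41 for mineralizing osteoblast genes, cluster 9 has -0.96 for the same list, and cartilage matrix genes lie at -2.45 in connective tissue fibroblast-like cells.

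Both fibroblast-like classes had lower cartilage matrix genes in the mutant library, and connective tissue fibroblast-like cells also lower cell cycle genes. In connective tissue fibroblast-like cells, marked by Pi16 and Clec3b, 14 of 15 cartilage matrix genes were lower and 0 higher (median log2 -2.45, percentile 0), with Matn1 at 432 and 14.8 CPM, and 12 of 16 S phase and mitosis genes were lower and 0 higher (-1.09, percentile 0), with Mki67 at 51.7 and 14.6 CPM. In meningeal fibroblast-like cells, marked by Cldn11 and Gjb6, 9 of 15 cartilage matrix genes were lower and 0 higher (-1.14, percentile 0), with Col2a1 at 474 and 150 CPM, while S phase and mitosis genes had 1 of 15 higher and 3 lower (-0.29, percentile 5.25). The ratio of Matn1 to Col2a1 was 0.442 in control connective tissue fibroblast-like cells and 0.360 in control chondrocyte-like cells, against 0.0431 in control tendon and ligament-like cells, so the cartilage counts in these classes did not share 1 profile. The connective tissue value lay near the chondrocyte-like one, as chondrocyte RNA in those control cells would give. The lower cartilage genes there thus need not be a difference of the fibroblasts. Any bearing on the cell cycle genes was not tested. Dissociation stress genes were lower in both classes as well, with 0 of 18 higher and 5 lower in connective tissue (-0.35, percentile 0) and 0 higher and 3 lower in meningeal fibroblast-like cells (-0.32, percentile 0), so handling or quality was not ruled out. Hhip was higher in meningeal fibroblast-like cells (2.57 and 9.58 CPM), and in connective tissue fibroblast-like cells it had 26.6 and 37.1 CPM.

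The osteoblast-like cluster, with 112 control and 443 mutant cells and so below the 200 cells set for a comparison of classes, was described after its values were seen. Bglap (ENSMUSG00000074483, chromosome 3, 88383501 to 88384464, minus strand, GRCm38) had 494 CPM in control and 9.11 CPM in mutant, and its neighbouring copy Bglap2 286 and 5.39 CPM. Reads can be shared between these near-identical genes. Of 18 mineralizing osteoblast genes, 3 were higher and 7 lower (median log2 -0.40, percentile 0). Ibsp was among the higher ones at 20916.5 and 32823.4 CPM, as was Mepe, an osteocyte gene (14.0 and 73.3 CPM), and outside that list Hhip was higher (27.7 and 131 CPM). Of 18 genes of the PTH and cAMP-PKA response, 7 were higher and 0 lower (median log2 0.53, percentile 100), including Mmp13 (9.85 and 64.7 CPM), Tnfsf11 (4.15 and 22.9 CPM) and Rgs2 (49.3 and 138 CPM). Of 19 BMP and TGF-beta pathway genes, 8 were higher and 2 lower (0.56, percentile 100), with Id1 at 68.5 and 179 CPM. Cartilage matrix genes had 12 of 16 lower and 0 higher (-2.18, percentile 0), and in all osteoblast-like cells Matn1 had 434 and 8.18 CPM and Col2a1 1205.1 and 263 CPM, with the chondrocyte-like ratio of 0.360 in control, as chondrocyte RNA in control cells would give. Bglap also led this cluster, and 5 control cells held 50.3% of its Bglap and Bglap2 UMIs.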

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

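The tests of sex for the Col10a1 and Hedgehog patterns and of a few control cells for the Bglap pattern were set before their results were seen, and the other tests here were chosen only afterwards, as was the median of 0.25 above which list medians were set against each other.

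A first group of results had list medians on opposite sides of 0 in different classes, and none of these differences between classes was tested. Mineralizing osteoblast genes had a median log2 ratio of 1.41 in chondrocyte-like cells and -0.96 in cluster 9, a difference of 2.37. The cluster 9 median rests on summed UMIs, and the thinned shares of its cells with an Ibsp or Spp1 UMI had overlapping intervals. Osteoclast regulators had 1.02 in chondrocyte-like cells and -0.32 in cluster 9, a difference of 1.34. Single chondrocyte-like clusters gave less, with 0.050 in cluster 3, -0.529 in cluster 1 and at most 0.737, in cluster 12. Interferon response genes had 0.67 in chondrocyte-like cells and -0.41 in cluster 9, a difference of 1.08. Within chondrocyte-like clusters 1, 3 and 10 this median was -0.951, -0.779 and -0.794, against 0.146, 0.763 and 0.739 in clusters 2, 12 and 19. The pooled value can thus reflect the mix of clusters. Adipocyte differentiation genes had 0.38 in tendon and ligament-like cells and -0.38 in chondrocyte-like cells, a difference of 0.76. Chondrocyte-like clusters 2 and 12 had 0.237 and 0.521 for this list, while clusters 1, 3, 10 and 19 had -1.206, -0.439, -0.904 and -0.154. Dissociation stress genes had 0.27 in cluster 9 and -0.35 in connective tissue fibroblast-like cells, a difference of 0.62. Blood cell RNA had 4.49 in meningeal fibroblast-like cells, with genes at 0 set to the 3-count floor, and -4.13 in cluster 6, a difference of 8.62.

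Col10a1 was higher and Ucma lower in mutant chondrocyte-like cells, by log2 ratios of 3.11 and -3.01. The mix of sexes was excluded as the source, since cells with Y-linked UMIs had less Col10a1 than cells with Xist UMIs in both libraries, with a higher value of -0.26 where at least 1.56 was needed. Free RNA alike in all droplets was argued against because, among the mesenchymal classes and clusters compared, the next highest had 0.42% of the chondrocyte-like Col10a1 level, although the few mutant macrophage-like cells, outside that test, held a thinned mean of 1.58 UMIs against 14.3 for a reason not tested. Depth was argued against because the thinned ratios were 3.52 and, for Ucma, -2.98. In cluster 3, shared by both libraries, Col10a1 differed by 3.21 at low levels (1.27 and 11.8 CPM) and Ucma by -1.57, so other pieces of cartilage or another stage in the mutant library cannot be told apart from an effect of the genotype, which may underlie the pattern as a hypothesis only. The mutant Col10a1 level in cluster 3 was also near that of cluster 9, at 0.42% of the pooled chondrocyte-like level. Free RNA was thus not ruled out for the Col10a1 difference within cluster 3.

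Bglap and Bglap2 were lower in the mutant osteoblast-like cluster by a log2 ratio of -5.75, although Ibsp was higher there. UMIs moved between copies were excluded, since the sum of Bglap, Bglap2 and Bglap3 gave -5.74. Control chondrocyte-like cells had 0.036% of the level, so chondrocyte doublets or free chondrocyte RNA could not supply it. That outcome was likely beforehand, since both genes were osteoblast markers used for naming and Bglap led the cluster. It therefore lends little support, and RNA from other cells was not examined. A few control cells did matter: 5 of 112 held 50.3% of the UMIs, as that explanation predicted. Without them the ratio was still -4.81, a value known before it was made a test, and a UMI was found in 54 of 112 control cells (48.2%, 38.7 to 57.9) and 34 of 443 mutant cells (7.67%, 5.37 to 10.6), unthinned. The size thus rests partly on few cells, and whether the rest reflects the genotype, the stage of the osteoblasts or the dissected part of the skull could not be tested.

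Hhip, Ptch1 and Gli1 together were higher outside chondrocyte-like cells of the mutant library, by a log2 ratio of 1.51. Free RNA or doublets of chondrocyte-like cells were excluded: their Hhip level was 11.7% of that in mutant tendon and ligament-like cells, and by the Col2a1 of each mutant class at most 1.72% of the level of any of the 3 genes there could have been carried over. The mix of sexes was excluded, with a higher within-library value of 0.20 where at least 0.75 was needed. Over 12 finer clusters the median was 1.26, and 11 were higher, with a range from -0.50 to 2.42, so another mix of cells within the classes cannot be told apart for all of them. Ihh was also higher in mutant chondrocyte-like cells, and Hedgehog signalling from cartilage to its neighbours may be one candidate explanation, which these libraries do not decide.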

How the results depend on the processing

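The automatic doublet threshold, the naming rules, clustering without the fixed markers, leaving out shallow clusters and thinning to 2000 UMIs were chosen after seeing the data, and the other alternatives before. Of 850 values recomputed, 566 stayed within the counting error of the main value or, for counts of lists or genes, within 1.5-fold of it. Another 276 moved by more than that and 8, whose main value had stood out, reversed. From main values that had not stood out, 9 more changed sign. The cause was not tested. No paired analysis was possible because each genotype has 1 library and no test was made, and leaving out replicates was not possible. All 24 named genes of mesenchymal cells kept their direction in each of 10 alternatives. They had been picked from these data for extreme ratios and like signs across classes, which made this likely beforehand. With classes weighted equally, 3 lists lay in the highest 2.5% of random lists in place of 13, and medians reversed for PTH and cAMP-PKA response (-0.031), osteogenic transcription factors (-0.037) and the Wnt pathway (-0.00028), and the medians of the Hedgehog pathway (-0.122), interferon response (-0.251) and blood cell RNA (-0.108), which had not stood out, also changed sign, as did S phase and mitosis (0.098) with cells weighted equally. With all barcodes, tendon and ligament-like cells reversed for Trh (-1.044), Cnmd (0.893), Cd74 (0.541) and Col9a1 (0.509). The log2 ratio of Pth1r, 1.48 in mesenchymal cells, was 1.413 with TMM, 1.426 with median-of-ratios and 1.560 with cells weighted equally; in chondrocyte-like cells, 2.22, it was 2.279 with stricter cells, 2.167 with the automatic doublet threshold, 2.322 with cells weighted equally and 2.418 thinned. The difference in chondrocyte-like share, -26.5 points, was -33.6 with stricter cells, -24.4 with the automatic doublet threshold, -29.9 without shallow clusters, -33.9 at resolution 2, -24.6 without the fixed markers, -15.7 with each library clustered alone and -20.6 with the first naming rule. That of osteoblast-like cells, 4.61 points, was 16.1 with stricter cells, 15 with all barcodes, 3.32 with doublets kept, 3.06 with the automatic threshold, 11.5 at resolution 2, 11.9 with libraries alone, 17.3 and 13.3 with the first and second naming rules, 17.5 with no gap and 7.34 by score per cell. The tendon and ligament-like share reversed to -0.709 points at resolution 2. The cycling difference in mesenchymal cells, 0.517 points, was 1.76 with the automatic threshold, -4.64 unthinned and 1.22 thinned to 2000 UMIs, and in chondrocyte-like cells, -7.59 points, it was -5.45 with the automatic threshold, -10.3 with 2 or more genes, -11.5 unthinned and -1.59 thinned to 2000 UMIs. Scaling moved the log2 ratios of mesenchymal cells by -0.065 with TMM and -0.052 with median-of-ratios. Depth limits the classes of few or shallow cells most, such as the 12 control macrophage-like cells.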

Other observations

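The comparisons given here were chosen after the values were seen, and no explanation of them was tested. In the osteoblast-like cluster, Notch pathway genes had 4 of 6 measured genes higher and 0 lower in the mutant library (median log2 1.22, percentile 99.98), with the target Hey1 at 2.85 and 17.4 CPM and Notch1 at 6.22 and 16.5 CPM. Wnt pathway genes there had 7 of 17 higher and 3 lower (0.64, percentile 100), with Wnt4 at 13.0 and 53.1 CPM and Sfrp2, a secreted Wnt antagonist, at 47.7 and 20.7 CPM. Adipocyte differentiation genes had 5 of 9 higher and 1 lower (0.62, percentile 99.15), with Lpl at 2.85 and 8.65 CPM. Serpinf1, the gene for the antiangiogenic factor PEDF, had 2428.2 and 996 CPM.

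Haemoglobin RNA differed by class and in opposite directions. In cluster 6, Hbb-bs had 22.4 CPM in control and 1.28 CPM in mutant, and Hba-a1 had 13.3 and 0.232 CPM. In tendon and ligament-like cells Hba-a1 had 6.55 and 0.429 CPM. In meningeal fibroblast-like cells Hbb-bs had 0 counts in control and 28.6 CPM in mutant, and Hba-a1 0.643 and 18.1 CPM. These cells were sorted by their reporter, and red cell RNA was not analysed further.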
